A study of Mus musculus with 18 samples.

How the data were processed

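Poly(A) RNA of 18 cultures of primary mouse Leydig cells was sequenced with a stranded library kit, per the labels' protocols. The authors deposited 1 table of raw read counts per gene, with 55487 genes and a column for each of the 18 libraries. The submitters' processing notes name HISAT2 and HTSeq and the mm10 build, without versions, and neither the annotation nor the strand setting of the counting is recorded. Libraries were assigned to the 6 groups from the column names and the labels. Of the gene IDs, 55227 were found in the GENCODE annotation of GRCm38 (the mm10 assembly), from which the coordinates were taken, and 236 IDs share a symbol with another. Library totals ranged from 15201530 to 23898435 counts.

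CPM values, which are counts scaled by TMM to a common library size, and all tests were computed from the deposited counts. The tests used edgeR 4.0.16 in R 4.3.3 with TMM scaling and filterByExpr, which kept 16432 genes, and a quasi-likelihood fit (glmQLFit, robust) of 6 group means to all 18 libraries with 12 residual degrees of freedom. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 within each of 10 contrasts. These were the H2O2 effect and the fluvastatin effect in each siRNA arm, the knockdown effect in each of the 3 treatments and its average, and the interactions of H2O2 and of fluvastatin with knockdown. Principal components used log2 CPM with a prior count of 2. Prdx1 was also tested by an exact permutation of its log2 CPM within treatment. Fold changes of pairs of contrasts were correlated across genes, and where the contrasts shared libraries the values were set beside the mean of 20 simulations of unchanged groups drawn with the fitted dispersions.

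The contrasts, the tests, the rule for named genes and 30 gene lists were fixed before the data were examined. The lists covered cholesterol synthesis, liver X receptor targets, NRF2 targets, antioxidant enzymes, p53 targets, immediate early genes, endoplasmic reticulum stress and the integrated stress response, heat shock, steroid synthesis, NF-kappaB targets, interferon-stimulated genes, the cell cycle, apoptosis, ferroptosis, actin and SRF/MRTF targets, YAP/TEAD targets, autophagy and lysosome, extracellular matrix, mitochondrially encoded transcripts, oxidative phosphorylation, glycolysis and hypoxia, and replication-dependent histones. Markers of macrophages, Sertoli cells, smooth muscle, fibroblasts, endothelium, germ cells and erythrocytes made up the rest. The 28 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within a contrast, with an estimated correlation as an alternative. A member is said to have risen or fallen where it passed over all genes tested, and a second count (list-adjusted) is adjusted over the list alone.

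Genes named by size passed the test, averaged at least 1 CPM, did not overlap between the groups compared and carried a symbol that is not a clone name. They were the 8 largest rises and falls for the effects of H2O2 and fluvastatin in siNC, for knockdown without H2O2 and for its average, and the 4 largest in each direction for the other pairwise contrasts. In the interactions they were the 4 smallest p in each direction. Up to 4 members per list and a fixed set that includes Prdx1, Star and Cyp11a1 were added. Some genes that this rule names, and 1 of the lists, are not reported here. Genes near-identical to Prdx1 were sought with blastn 2.17.0+ at 90% identity or more over at least 100 bp.

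The labels number the replicates 1 to 3 in every group without saying that a number marks a shared animal or day. Same-numbered libraries deviated together by the rule of a correlation over 0.1 in every pair for the H2O2 effect in siNC, where the correlations were 0.135, 0.135 and 0.118. The pairing of that contrast comes from this check of the data and not from the labels. Pairs of replicates differed by 2.74 to 17.1 times counting noise (chi-square per degree of freedom), so none were copies of a library. The spread used to judge correlations under other settings was a jackknife standard error over fits that left out 1 library.

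Alternatives fixed beforehand were RLE size factors, no low-count filter, the replicate block, an estimated inter-gene correlation, fits to only the groups compared, limma voom, DESeq2 1.42.0, a minimum absolute log2 fold change of 1, and leaving out each library in turn. Scaling by library size alone, offsets for GC content and transcript length (with and without the block), and leaving out both siprdx1+H2O2 libraries at the ends of a GC-linked axis were added after the data were seen. The steps were tested on simulated data drawn from the real means and library sizes with a set of changed genes. For the H2O2 effect in siNC edgeR recovered 55.2%, 85.1% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold among 16432 genes, and 5.6% of its calls were false. For the H2O2 interaction it recovered 49.3%, 76.1% and 86.4%, with 6.8% false, and for the averaged knockdown 83.6%, 95.5% and 100%, with 1.9% false. Those simulated libraries held no GC trend. With a GC trend planted and no offsets, recovery was 41.8%, 70.1% and 93.9% for H2O2 in siNC. It was then 11.9%, 38.8% and 86.4% for the H2O2 interaction and 76.1%, 92.5% and 100% for the averaged knockdown. No library was left out of the main tests.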

Results

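RNA was sequenced from mouse Leydig cells, the testosterone-producing cells of the testis, in primary culture. The cells carried either a control siRNA (siNC) or an siRNA against Prdx1 (siprdx1), which encodes peroxiredoxin 1, an enzyme that breaks down hydrogen peroxide (H2O2). Each siRNA arm held 3 groups of 3 libraries. The first had no H2O2, the second had 200 µM H2O2 for 30 min, and the last had H2O2 and then 5 µM fluvastatin (FV), a statin, for 6 h. Groups without fluvastatin had 0.1% DMSO for those 6 h. No DMSO is recorded for the fluvastatin groups, so as described each fluvastatin comparison also differs in vehicle, and no group had fluvastatin without H2O2. The siNC libraries held 21568170, 22187255 and 23153078 counts, and siNC+H2O2 held 17683846, 18557448 and 22933161. The siNC+H2O2+FV libraries held 18899222, 21569794 and 23168229 and the siprdx1 libraries 18451144, 22598651 and 15201530. The siprdx1+H2O2 libraries held 19705974, 23585595 and 23898435 and the siprdx1+H2O2+FV libraries 23455026, 22886591 and 16773112. The common biological coefficient of variation was 7.01%, with 3 libraries per group. The labels call the replicates biological and do not say whether they came from separate animals.

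Prdx1 (ENSMUSG00000028691, chromosome 4, 116685544 to 116700822, GRCm38) was lower in every siprdx1 library than in every siNC library. Without H2O2 its level was 1345, 1358 and 1279 CPM (counts scaled to a common library size) in siNC and 498, 426 and 468 CPM in siprdx1. After H2O2 it was 1690, 1648 and 1558 CPM in siNC and 576, 485 and 511 CPM in siprdx1. After H2O2 and fluvastatin it was 1524, 1528 and 1460 CPM in siNC and 559.9, 519 and 547 CPM in siprdx1. The knockdown left 35%, 32.1% and 36% of the mean level in the 3 conditions, with log2 fold changes of -1.52 ± 0.06, -1.64 ± 0.06 and -1.47 ± 0.06 (SE, n = 3 per group). An exact two-sided permutation test of 9 against 9 libraries within treatment gave a mean log2 difference of -1.54 and p = 0.00025, the smallest that its 8000 permutations can give. In siNC cells H2O2 raised Prdx1 by 0.30 ± 0.06 (edgeR adjusted p = 0.00403). Fluvastatin gave -0.12 ± 0.06 in siNC, which did not pass (edgeR adjusted p = 0.179) but passed at -0.22 with counts scaled by library size alone and at -0.16 with GC and length offsets. In siprdx1 fluvastatin gave Prdx1 a value of 0.05 ± 0.06 (edgeR adjusted p = 0.642), which turned to -0.05 with library size alone and to -0.004 without siprdx1+H2O2 replicate 2. The near-identical Gm21399 (98.3% identity over 597 bp) and Gm7204 (97.5%) also fell with knockdown, by 1.57 ± 0.08 and 1.21 ± 0.22 on the log2 scale, and their values are uncertain because the counting could split reads between them and Prdx1.

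**Figure D1:**
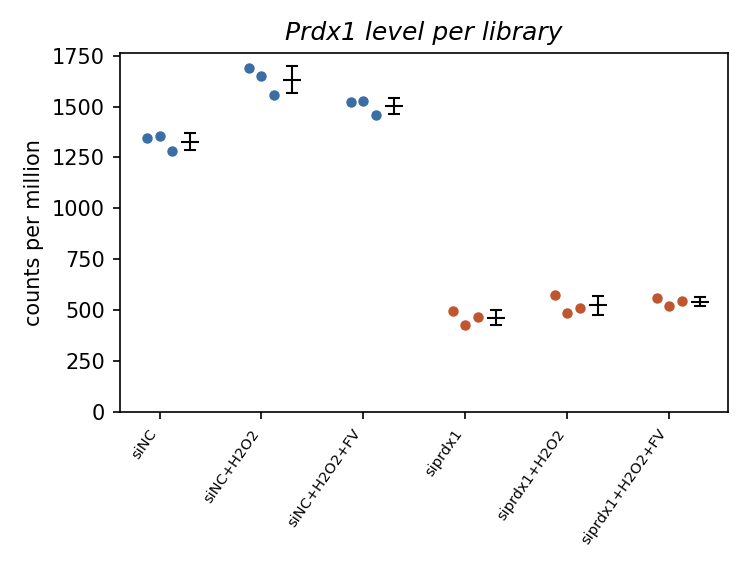
Prdx1 level by group in CPM, with the 3 libraries of a group as points beside their mean and SD, siNC in blue and siprdx1 in orange. The 9 siprdx1 libraries lie between 426 and 576 CPM and the 9 siNC libraries between 1279 and 1690 CPM.

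The cultures expressed some steroidogenic genes next to abundant macrophage genes. Over all 18 libraries, Cyp11a1, which cleaves cholesterol to pregnenolone, averaged 712 CPM, Star, which carries cholesterol into mitochondria, 286 CPM and Insl3 50.4 CPM. The Leydig markers Cyp17a1 and Hsd17b3 were barely detected, with averages of 0.0318 and 0.067 CPM. The cultures thus did not express the full set of Leydig genes. The macrophage markers Lyz2, Ctss and Cd68 averaged 5677, 636 and 438 CPM, and the fibroblast marker Col1a1 3716 CPM. All 17 macrophage markers were expressed enough to be tested, and none is in another list. Of the germ cell list 2 of 14 members were expressed enough to be tested, and of the erythrocyte list 0 of 7, so neither list was tested as a set. The first principal component (35.8% of variance) set the fluvastatin groups apart from the others in both siRNA arms. The second (11.9%) set H2O2 without fluvastatin apart from no H2O2.

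**Figure D2:**
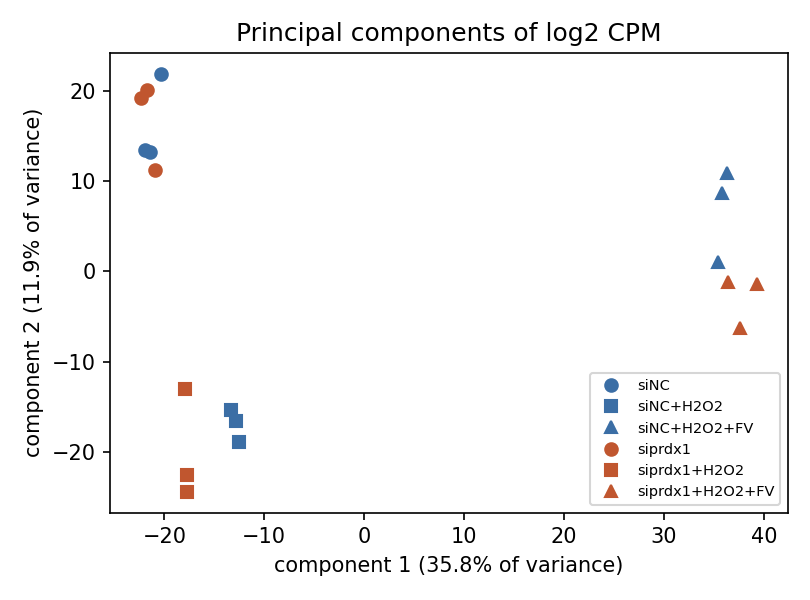
Component 1 (horizontal, 35.8% of variance) and component 2 (vertical, 11.9%) of log2 CPM, each point a library, coloured by siRNA (siNC blue, siprdx1 orange) and shaped by treatment. The fluvastatin libraries lie to the right, at 35.4 and above on component 1, and the others at -12.6 and below.

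The H2O2 effect was read in siNC cells (siNC+H2O2 against siNC). Immediate early genes, which cells switch on within minutes, were among the largest rises, read here after the later 6 h. Arc (ENSMUSG00000022602, chromosome 15, 74669083 to 74672570) rose by 5.13 ± 0.12 on the log2 scale, and Fos (ENSMUSG00000021250, chromosome 12, 85473890 to 85477273) went from 19.4 ± 1.45 to 256 ± 8.05 CPM (SD, n = 3), a log2 change of 3.72 ± 0.07. Other large rises were Fosb (3.05 ± 0.12), Ier2 (2.91 ± 0.09), Egr1 (2.32 ± 0.06), Btg2 (2.74 ± 0.04), Rgs1 (2.60 ± 0.13) and H4f16 (3.86 ± 0.44), all given as log2 fold change ± SE with n = 3 per group, here and below. H4f16, like Hspa1a, Ifit3 and Ifit3b below, has near-identical copies that could take its reads, so its value is uncertain. The largest falls included the imprinted long noncoding RNAs Kcnq1ot1 (-1.76 ± 0.15) and Meg3 (-1.33 ± 0.06), of which Kcnq1ot1 lies antisense to Kcnq1 and is uncertain because the strand setting of the counting is not recorded. Others were Spaca6 (-1.36 ± 0.07), Col20a1 (-1.29 ± 0.23), Hoxc5 (-1.29 ± 0.19), Sec31b (-1.18 ± 0.25) and Cd46 (-1.16 ± 0.22).

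Among the gene lists, immediate early genes led, as 16 of 24 tested members rose (19 when adjusted over the list alone, called list-adjusted below), camera adjusted p = 2.33e-166. In the list for endoplasmic reticulum stress and the integrated stress response, 9 of 23 tested members rose (15 list-adjusted), camera adjusted p = 4.26e-12, including the regulator Atf4 (0.62 ± 0.05) and Ppp1r15a (0.93 ± 0.07). NF-kappaB targets and inflammatory mediators followed, as 10 of 23 tested members rose (11 list-adjusted), camera adjusted p = 7.84e-12, among them the chemokine Cxcl1 (1.24 ± 0.13) and Tnf (0.85 ± 0.08). Of heat shock genes 6 of 18 tested members rose (7 list-adjusted), camera adjusted p = 6.68e-09. These included Dnajb1 (1.02 ± 0.06) and Hspa1a (0.98 ± 0.09). Among targets of NRF2, the regulator of antioxidant genes, 5 of 24 tested members rose (12 list-adjusted), camera adjusted p = 1.82e-06. Examples were Nqo1 (0.41 ± 0.07), Srxn1 (0.35 ± 0.05) and Hmox1 (0.25 ± 0.05). For antioxidant enzymes other than Prdx1, 2 of 27 tested members rose (7 list-adjusted), camera adjusted p = 0.000499. Among cholesterol synthesis genes, 4 of 25 tested members rose and 0 fell (10 and 1 list-adjusted), camera adjusted p = 0.000217. An example was Insig1 (0.46 ± 0.06). In the p53 list 4 of 24 tested members rose (4 list-adjusted), camera adjusted p = 9.56e-14. They were Btg2, Plk2 (1.71 ± 0.06), Gdf15 (1.00 ± 0.13) and Cdkn1a (0.29 ± 0.06). In the histone list, 4 of 9 tested members rose (5 list-adjusted), camera adjusted p = 0.000159. An example was H1f4 (1.97 ± 0.40).

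Mitochondrially encoded transcripts moved down, as 5 of 13 tested members fell (6 list-adjusted), camera adjusted p = 0.000614, adjusted p = 0.195 with an estimated correlation, while among nuclear-encoded subunits of oxidative phosphorylation 5 of 31 tested members rose (13 list-adjusted), camera adjusted p = 1.76e-06, adjusted p = 0.13 with an estimated correlation. The mitochondrial share of counts was 1.38% ± 0.022 in siNC and 1.18% ± 0.05 in siNC+H2O2 (SD, n = 3). The share of long noncoding RNAs was 0.919% ± 0.034 and 0.713% ± 0.011. Noncoding genes made up 164 of the 755 lower genes (21.7%) and 1598 of the 16432 tested (9.72%), with Fisher's exact test p = 9.49e-24 across genes, which are not independent. Among macrophage markers, 2 of 17 tested members rose (7 list-adjusted), camera adjusted p = 0.00101. Among genes of steroid synthesis and Leydig identity, 2 of 21 tested members rose (3 list-adjusted), camera adjusted p = 0.00207, 1 of them Nr4a1 (1.11 ± 0.08), which is also in the immediate early list, while Star (0.02 ± 0.05) and Cyp11a1 (0.03 ± 0.04) did not pass, and the value of Star turned to -0.005 without siNC replicate 3 and to -0.03 without siNC+H2O2 replicate 2.

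In all, 1142 of 16432 tested genes differed, 387 higher and 755 lower (edgeR, adjusted p below 0.05), and 163 of them by at least 1 on the log2 scale. Single libraries mattered for this count, which was 653 without siNC replicate 2, 729 without siNC replicate 3, 660 without siNC+H2O2 replicate 1 and 655 without siNC+H2O2 replicate 3. Among the lists, the NF-kappaB count that rose became 5 without siNC replicate 2 and 6 without siNC+H2O2 replicate 3, the cholesterol count that rose became 2 without siNC replicates 2 or 3 or siNC+H2O2 replicates 1 or 3, the mitochondrial count that fell became 2 without siNC replicate 3 or siNC+H2O2 replicates 2 or 3 and 3 without siNC replicate 2, the oxidative phosphorylation count that rose became 0 without siNC replicate 2 or siNC+H2O2 replicate 3 and 2 without siNC replicate 3 or siNC+H2O2 replicate 1 and the histone count that rose became 2 without siNC replicates 2 or 3 or siNC+H2O2 replicates 1 or 2. Over single omissions smaller counts ranged over 1 to 2 for macrophage markers that rose, 1 to 3 for antioxidant enzymes that rose and 1 to 4 for steroid synthesis genes that rose.

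Fluvastatin was then read in siNC cells after H2O2. Transcription factors of the early response rose steeply. Egr3 (ENSMUSG00000033730, chromosome 14, 70077203 to 70082614) rose by 7.80 ± 0.09, and Nr4a3 (6.55 ± 0.13), Egr4 (6.14 ± 0.29), Fosb (4.80 ± 0.08) and Nr4a1 (4.59 ± 0.08) rose with it. Rassf6 (5.90 ± 0.53), Dlx3 (5.67 ± 0.58) and Eid3 (4.33 ± 0.28) were among the largest rises too. Among the largest falls were Pabpc4l (-2.23 ± 0.20), Ppp1r3c (-2.21 ± 0.27), Zkscan4 (-1.89 ± 0.23), Kbtbd11 (-1.89 ± 0.29), Adamts15 (-1.79 ± 0.18), Zc2hc1c (-1.70 ± 0.37), Klf15 (-1.67 ± 0.10) and Tfap4 (-1.66 ± 0.18). Star (ENSMUSG00000031574, chromosome 8, 25806555 to 25815982) rose by 1.34 ± 0.05.

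Targets of the actin-sensing factors SRF and MRTF and genes of the actin cytoskeleton were higher with fluvastatin: 20 of 20 tested members rose (20 list-adjusted), camera adjusted p = 2.58e-26. Among them were Vcl (1.04 ± 0.05), Srf (1.88 ± 0.09), Filip1l (1.11 ± 0.06) and Tpm1 (0.90 ± 0.05). For YAP/TEAD targets 11 of 17 tested members rose and 2 fell (11 and 3 list-adjusted), camera adjusted p = 6.33e-16. These included F3 (3.29 ± 0.05), Nuak2 (1.86 ± 0.07) and Ccn2 (0.83 ± 0.05). Of immediate early genes 20 of 24 tested members rose and 1 fell (21 and 1 list-adjusted), camera adjusted p = 1.62e-181, and of smooth muscle markers 8 of 10 tested members rose (8 list-adjusted), camera adjusted p = 1.19e-08. Examples were Acta2 (1.02 ± 0.07), Cnn1 (1.95 ± 0.18) and Lmod1 (1.48 ± 0.07). Interferon-stimulated genes went the other way: 1 of 28 tested members rose and 23 fell (1 and 24 list-adjusted), camera adjusted p = 1.1e-08. Among them were Ifit3 (-1.12 ± 0.09), Rtp4 (-0.90 ± 0.10), Oasl2 (-0.56 ± 0.06) and Stat2 (-0.51 ± 0.06). For NRF2 targets 9 of 24 tested members rose and 0 fell (10 and 3 list-adjusted), camera adjusted p = 5.45e-10, and library size alone gave 8 higher and 6 lower. Rises were Txnrd1 (1.60 ± 0.04), Srxn1 (1.55 ± 0.05), Gclc (1.37 ± 0.06) and Hmox1 (1.26 ± 0.05). Of cholesterol synthesis genes 11 of 25 tested members rose and 3 fell (11 and 5 list-adjusted), camera adjusted p = 0.0363. These included Hsd17b7 (0.84 ± 0.06) and Insig1 (0.37 ± 0.06). Among heat shock genes, 10 of 18 tested members rose and 1 fell (10 and 1 list-adjusted), camera adjusted p = 1.62e-09. Examples were Dnajb1 (1.88 ± 0.05) and Dnajb4 (2.06 ± 0.10). In the NF-kappaB list 13 of 23 tested members rose and 4 fell (15 and 4 list-adjusted), camera adjusted p = 5.43e-10. Among them were Lif (2.79 ± 0.10) and Ptgs2 (3.73 ± 0.15).

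Among mitochondrially encoded transcripts, 9 of 13 tested members rose (9 list-adjusted), camera adjusted p = 0.002, adjusted p = 0.241 with an estimated correlation, and their share of counts was 1.44% ± 0.127 (SD, n = 3). Among extracellular matrix genes, 7 of 24 tested members rose (8 list-adjusted), camera adjusted p = 2.51e-08. An example was Thbs1 (2.23 ± 0.04). Among macrophage markers, beside the fall of the interferon list, 1 of 17 tested members rose and 6 fell (1 and 6 list-adjusted), camera adjusted p = 0.102. For steroidogenesis and Leydig cell identity 6 of 21 tested members rose and 4 fell (6 and 6 list-adjusted), camera adjusted p = 0.00232, with a median of -0.06, a mean of 0.23 and the test pointing up, while scaling by library size alone gave 3 higher and 8 lower. Star, Fdx1 (1.06 ± 0.07) and Nr2f2 (-1.31 ± 0.07) were among those that passed, and Cyp11a1 had 0.06 ± 0.04, which did not pass and was -0.04 with library size alone. In total 4090 genes differed, 2226 higher and 1864 lower (edgeR), 585 of them by at least 1 on the log2 scale. Scaling by library size alone gave 1474 higher and 3835 lower, since it moved the median of all genes by -0.10, so these directions are relative to the median gene. With 1 library left out, the cholesterol count that rose became 6 without siNC+H2O2 replicate 3 and 7 without siNC+H2O2+FV replicate 1, the cholesterol count that fell became 1 without siNC+H2O2 replicate 3, the mitochondrial count that rose became 5 without siNC+H2O2+FV replicate 1, the steroid count that rose became 3 without siNC+H2O2 replicate 1 and the steroid count that fell became 2 without siNC+H2O2 replicates 1 or 3 or siNC+H2O2+FV replicate 2. Counts of few genes spanned over such omissions 0 to 2 for NRF2 targets that fell and 1 to 2 for YAP/TEAD targets that fell.

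To see what Prdx1 knockdown changed without any peroxide, siprdx1 was compared with siNC. Genes of the extracellular matrix were lower. Eln (ENSMUSG00000029675, chromosome 5, 134702593 to 134747323), the gene of elastin, went from 299 ± 23.7 to 139 ± 4.91 CPM, a change of -1.11 ± 0.06, and Thbs2 (-0.62 ± 0.05), Lox (-0.61 ± 0.07) and Fn1 (-0.59 ± 0.06) fell too. Other large falls were Scel (-1.22 ± 0.24), Fpr1 (-0.99 ± 0.17) and Marco (-0.92 ± 0.06), of which Fpr1 and Marco encode receptors of phagocytes. Rises that held without any single library included Sh2d6 (1.57 ± 0.14), Cxcl10 (1.11 ± 0.14) and Slc15a2 (0.94 ± 0.18).

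For the extracellular matrix list 18 of 24 tested members fell and 0 rose (20 and 1 list-adjusted), camera adjusted p = 8.84e-60. In the fibroblast and stromal list, which shares collagens with it, 4 of 11 tested members fell and 0 rose (6 and 1 list-adjusted), camera adjusted p = 1.67e-06. Examples were Col3a1 (-0.44 ± 0.05) and Mfap5 (-0.46 ± 0.08). For actin and SRF/MRTF targets 6 of 20 tested members fell (8 list-adjusted), camera adjusted p = 2.79e-09. An example was Fhl2 (-0.36 ± 0.05). Among smooth muscle markers, 5 of 10 tested members fell and 0 rose (6 and 1 list-adjusted), camera adjusted p = 2.51e-06. Genes of endoplasmic reticulum stress and the integrated stress response went up: 9 of 23 tested members rose (11 list-adjusted), camera adjusted p = 2.05e-16. These included Asns (0.42 ± 0.06), Trib3 (0.75 ± 0.11), Hspa5 (0.33 ± 0.05) and Hyou1 (0.31 ± 0.05). Among NRF2 targets, 3 of 24 tested members rose and 0 fell (6 and 1 list-adjusted), camera adjusted p = 0.000803, adjusted p = 0.0501 with an estimated correlation. Examples were Txnrd1 (0.40 ± 0.04), Nqo1 (0.48 ± 0.07) and Gclc (0.33 ± 0.06). In the NF-kappaB list 4 of 23 tested members rose and 1 fell (8 and 1 list-adjusted), camera adjusted p = 9.82e-06, and of interferon-stimulated genes 2 of 28 tested members rose and 0 fell (4 and 1 list-adjusted), camera adjusted p = 0.00622. Among macrophage markers, 1 of 17 tested members fell and 0 rose (1 and 1 list-adjusted), camera adjusted p = 0.43. In all 383 genes differed, 108 higher and 275 lower (edgeR), with 163 higher and 199 lower under library size alone. The count was 207 without siNC replicate 3, 231 without siprdx1 replicate 1 and 212 without siprdx1 replicate 3. Among lists, the stress response count that rose became 5 without siNC replicate 3, the NF-kappaB count that rose became 1 without siNC replicates 1 or 3 or siprdx1 replicate 3, the actin count that fell became 2 without siprdx1 replicate 3 and the smooth muscle count that fell became 1 without siprdx1 replicate 3 and 3 without siNC replicates 1, 2 or 3 or siprdx1 replicate 1. Small counts ranged, over single omissions, from 0 to 1 for NF-kappaB targets and macrophage markers that fell and 1 to 2 for interferon-stimulated genes that rose.

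After H2O2, knockdown cells had lower immediate early genes than control cells. Fos was 256 ± 8.05 CPM in siNC+H2O2 and 116 ± 4.69 CPM in siprdx1+H2O2, and Arc (-1.65 ± 0.09), Fosb (-1.38 ± 0.09), Fos (-1.14 ± 0.06), Btg2 (-1.05 ± 0.04), Jun (-0.91 ± 0.07) and Egr1 (-0.82 ± 0.06) fell. For the immediate early list 12 of 24 tested members fell (13 list-adjusted), camera adjusted p = 3.26e-48. Extracellular matrix genes fell here too, as 12 of 24 tested members fell and 0 rose (18 and 2 list-adjusted), camera adjusted p = 3.6e-19. Among them were Eln (-0.83 ± 0.06) and Fn1 (-0.43 ± 0.06). Among fibroblast markers, 2 of 11 tested members rose and 3 fell (4 and 5 list-adjusted), camera adjusted p = 0.62. Of cell cycle genes 5 of 29 tested members fell (7 list-adjusted), camera adjusted p = 9.61e-10. These included Cenpf (-0.81 ± 0.12), Cenpe (-0.70 ± 0.11) and Mki67 (-0.43 ± 0.06). For cholesterol synthesis 3 of 25 tested members fell (6 list-adjusted), camera adjusted p = 1.68e-08. An example was Insig1 (-0.34 ± 0.06). In the stress response list, 6 of 23 tested members rose and 1 fell (12 and 2 list-adjusted), camera adjusted p = 6.19e-07. Among them were Hyou1 (0.38 ± 0.05) and Herpud1 (0.35 ± 0.06). Among interferon-stimulated genes, 5 of 28 tested members rose (7 list-adjusted), camera adjusted p = 1.11e-06. An example was Irf7 (0.46 ± 0.05). Macrophage markers moved down beside the immediate early genes, as 2 of 17 tested members fell (9 list-adjusted), camera adjusted p = 6.19e-07.

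The largest rises included Derl3 (1.58 ± 0.31) and Glp2r (1.05 ± 0.18). In all 448 genes differed after H2O2, 148 higher and 300 lower (edgeR). The siprdx1+H2O2 libraries 1 and 2 stood at opposite ends of an axis of variation within groups that followed transcript GC content (scores 22.8 and -19.3, Spearman rho -0.646 between loading and GC across 16410 genes). Without both, siprdx1+H2O2 held 1 library, assumed to vary like the others, and the count was 126. Derl3 then had 1.37 (adjusted p = 0.199) and Glp2r 0.83 (adjusted p = 0.153), and why these calls ended was not tested. It was 229 without siNC+H2O2 replicate 1, 281 without siNC+H2O2 replicate 2, 269 without siNC+H2O2 replicate 3 and 258 without siprdx1+H2O2 replicate 3. Among lists, the extracellular matrix count that fell became 6 without siprdx1+H2O2 replicate 3 and 7 without siNC+H2O2 replicate 1 and the interferon count that rose became 1 without siprdx1+H2O2 replicate 3, 2 without siNC+H2O2 replicates 1, 2 or 3 and 3 without siprdx1+H2O2 replicate 1. Small counts over single omissions spanned 0 to 2 for stress response genes that fell, 0 to 5 for macrophage markers that fell, 1 to 2 for fibroblast markers that rose and 2 to 5 for cholesterol synthesis genes that fell.

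With H2O2 and fluvastatin, knockdown cells had higher interferon-stimulated genes than control cells. Ifit3 (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), an interferon-induced antiviral gene, was 16.3 ± 0.96 CPM in siNC and 49.2 ± 2 CPM in siprdx1, a change of 1.59 ± 0.08, and Rsad2 (1.72 ± 0.12), Ifit3b (1.62 ± 0.13), Ifit1 (1.34 ± 0.09) and Irf7 (0.96 ± 0.06) rose as well. For the list 23 of 28 tested members rose (26 list-adjusted), camera adjusted p = 6e-91. Among NF-kappaB targets and inflammatory mediators, 9 of 23 tested members rose (12 list-adjusted), camera adjusted p = 5.06e-19. Examples were Cxcl5 (2.44 ± 0.27), Cxcl1 (1.06 ± 0.10), Tnf (0.63 ± 0.08) and Ccl2 (0.58 ± 0.08). Among stress response genes, 7 of 23 tested members rose and 0 fell (13 and 1 list-adjusted), camera adjusted p = 1.55e-14. Among them were Creld2 (0.73 ± 0.08), Herpud1 (0.46 ± 0.06) and Hspa5 (0.42 ± 0.05). The largest rise was that of Derl3 (2.70 ± 0.33), which acts in degradation of misfolded proteins. For NRF2 targets 5 of 24 tested members rose and 0 fell (13 and 1 list-adjusted), camera adjusted p = 8.78e-11. These included Nqo1 (0.63 ± 0.07) and Gclc (0.46 ± 0.05). Matrix genes were again lower: 13 of 24 tested members fell (17 list-adjusted), camera adjusted p = 1.01e-31. Examples were Eln (-0.91 ± 0.06), Fn1 (-0.74 ± 0.06) and Lox (-0.69 ± 0.07). Among fibroblast markers, 1 of 11 tested members rose and 3 fell (2 and 6 list-adjusted), camera adjusted p = 0.0111, adjusted p = 0.0795 with an estimated correlation, a call that ended without siNC+H2O2+FV replicate 3 (adjusted p = 0.0564). Among macrophage markers, beside the interferon list, 1 of 17 tested members fell and 0 rose (1 and 5 list-adjusted), camera adjusted p = 0.141. In all 652 genes differed, 266 higher and 386 lower (edgeR), and the count was 421 without siNC+H2O2+FV replicate 1, 329 without siNC+H2O2+FV replicate 2, 349 without siprdx1+H2O2+FV replicate 1, 370 without siprdx1+H2O2+FV replicate 2 and 412 without siprdx1+H2O2+FV replicate 3. With 1 library left out, the NRF2 count that rose became 3 without siprdx1+H2O2+FV replicate 1. Single omissions gave 0 to 1 for fibroblast markers and macrophage markers that rose.

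Averaged over the 3 treatments, the knockdown effect drew on all 18 libraries. Derl3, Sh2d6 (1.09 ± 0.08), Glp2r (1.00 ± 0.10), Gsta2 (0.93 ± 0.11), Cxcl10 (0.81 ± 0.07), Mest (0.76 ± 0.10), Slc15a2 (0.64 ± 0.11) and Mmp9 (0.61 ± 0.09) were the largest rises, with Derl3 at 1.90 ± 0.18. Apart from Prdx1 the largest falls were Trem1 (-1.07 ± 0.20), Anxa8 (-1.03 ± 0.15), Eln (-0.95 ± 0.04), Ptn (-0.90 ± 0.14), Scel (-0.89 ± 0.13), Ackr4 (-0.75 ± 0.10) and Fras1 (-0.73 ± 0.09). In the matrix list 20 of 24 tested members fell and 0 rose (21 and 1 list-adjusted), camera adjusted p = 7.85e-58, and of fibroblast markers 3 of 11 tested members rose and 6 fell (3 and 6 list-adjusted), camera adjusted p = 0.000521. In the stress response list 14 of 23 tested members rose and 0 fell (15 and 1 list-adjusted), camera adjusted p = 3.15e-20, and in the interferon list 21 of 28 tested members rose (25 list-adjusted), camera adjusted p = 1e-37. Of NRF2 targets 7 of 24 tested members rose and 1 fell (11 and 1 list-adjusted), camera adjusted p = 5.45e-08. Among them were Nqo1 (0.49 ± 0.04), Gclc (0.40 ± 0.03) and Slc7a11 (0.38 ± 0.07). For cell cycle genes 5 of 29 tested members fell (9 list-adjusted), camera adjusted p = 9.52e-07, and for cholesterol synthesis genes 6 of 25 tested members fell (12 list-adjusted), camera adjusted p = 9.53e-05. In steroid synthesis and Leydig identity 3 of 21 tested members rose and 3 fell (4 and 4 list-adjusted), camera adjusted p = 0.825. These included Cyp11a1 (-0.20 ± 0.03) and Lhcgr (0.46 ± 0.10). For macrophage markers 2 of 17 tested members fell and 0 rose (4 and 1 list-adjusted), camera adjusted p = 0.0966. In all 1542 genes differed, 645 higher and 897 lower (edgeR), 24 of them by at least 1 on the log2 scale. Under library size alone 977 were higher and 719 lower, so the split does not hold under that scaling. With 1 library left out, the cholesterol count that fell became 3 without siprdx1 replicate 3 and 10 without siprdx1+H2O2 replicate 1. Such omissions also gave 0 to 1 for matrix genes that rose and 2 to 4 for macrophage markers that fell.

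H2O2 was next tested in siprdx1 cells and for its interaction with knockdown. In siprdx1 cells H2O2 raised H4f16 (4.17 ± 0.48), Arc (3.38 ± 0.14), Fos (2.57 ± 0.07), Ier2 (2.04 ± 0.09), Egr1 (1.62 ± 0.06) and Junb (1.69 ± 0.09). The falls included Olfr1251 (-1.95 ± 0.27) and Cep290 (-1.82 ± 0.18). Of immediate early genes 12 of 24 tested members rose and 0 fell (17 and 1 list-adjusted), camera adjusted p = 2.08e-59, and of interferon-stimulated genes 9 of 28 tested members rose (13 list-adjusted), camera adjusted p = 8.37e-08. Examples were Irf7 (0.41 ± 0.05) and Isg15 (0.57 ± 0.10). For that list in siNC 5 of 28 tested members rose and 1 fell (8 and 1 list-adjusted), camera adjusted p = 0.000335, and in the interaction camera gave an adjusted p of 0.0536. Among extracellular matrix genes, 7 of 24 tested members rose (13 list-adjusted), camera adjusted p = 6.99e-08. Among them were Thbs2 (0.53 ± 0.05) and Eln (0.38 ± 0.06). Among fibroblast markers, 5 of 11 tested members rose (6 list-adjusted), camera adjusted p = 2.94e-05. For mitochondrially encoded transcripts 6 of 13 tested members fell (7 list-adjusted), camera adjusted p = 5.63e-09, and their share of counts was 1.4% ± 0.095 before and 1.1% ± 0.126 after H2O2 (SD, n = 3). Among NRF2 targets, 7 of 24 tested members rose and 1 fell (11 and 1 list-adjusted), camera adjusted p = 2.24e-05. In all 1293 genes differed, 407 higher and 886 lower (edgeR), with 234 higher and 1132 lower under library size alone. The count was 824 without siprdx1+H2O2 replicate 3 and 565 with replicate 3 alone in siprdx1+H2O2. With 1 library left out, the extracellular matrix count that rose became 4 without siprdx1 replicate 3 and 11 without siprdx1+H2O2 replicate 1 and the fibroblast count that rose became 2 without siprdx1 replicate 3 or siprdx1+H2O2 replicate 3 and 3 without siprdx1 replicate 1. The same omissions gave 0 to 1 for NRF2 targets that fell.

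The rise of immediate early genes with H2O2 was smaller in knockdown cells. In the interaction, which compares the 2 H2O2 effects, Fosb (-1.66 ± 0.19), Fos (-1.15 ± 0.10), Nr4a1 (-1.0 ± 0.11), Btg2 (-0.91 ± 0.06), Ppp1r10 (-0.89 ± 0.09), Plk2 (-0.89 ± 0.09), Jun (-0.85 ± 0.10) and Dnajb1 (-0.72 ± 0.08) fell, and Scara5 (0.43 ± 0.07) rose. For immediate early genes 9 of 24 tested members fell (14 list-adjusted), camera adjusted p = 2.31e-49. Of NF-kappaB targets 1 of 23 tested members fell (6 list-adjusted), camera adjusted p = 6.08e-08. Of cholesterol synthesis genes 0 of 25 tested members changed (1 lower list-adjusted, 2 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), camera adjusted p = 4.74e-05. Extracellular matrix genes moved up, as 1 of 24 tested members rose (5 list-adjusted), camera adjusted p = 2.21e-08. Macrophage markers moved down with the immediate early genes, as 0 of 17 tested members changed (1 lower list-adjusted, 4 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), camera adjusted p = 8.28e-05. In all 40 genes passed, 7 higher and 33 lower (edgeR). The count was 26 without siNC+H2O2 replicate 2 and 24 with replicate 3 alone in siprdx1+H2O2. Omitting any 1 library gave counts of 0 to 1 for NF-kappaB targets and cholesterol synthesis genes that fell and 0 to 1 for matrix genes that rose.

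Last came the response to fluvastatin under knockdown. In siprdx1 cells fluvastatin raised Egr3 (8.22 ± 0.09), Egr4 (7.88 ± 0.32), Nr4a3 (6.62 ± 0.13), Fosb (6.37 ± 0.09) and Star (1.40 ± 0.05), and Efna1 (-2.23 ± 0.26), Ppp1r3c (-2.09 ± 0.25), Trim63 (-2.05 ± 0.29) and Zfp108 (-2.04 ± 0.28) fell. Of immediate early genes 24 of 24 tested members rose (24 list-adjusted), camera adjusted p = 1.61e-246, of actin and SRF/MRTF targets 20 of 20 tested members rose (20 list-adjusted), camera adjusted p = 3.55e-29, and of NRF2 targets 11 of 24 tested members rose and 0 fell (11 and 1 list-adjusted), camera adjusted p = 2.83e-14. Among cholesterol synthesis genes, 11 of 25 tested members rose (14 list-adjusted), camera adjusted p = 0.000632. Among interferon-stimulated genes, most of which fell with fluvastatin in siNC, 8 of 28 tested members rose and 3 fell (8 and 5 list-adjusted), camera adjusted p = 0.389. These included Cxcl10 (1.43 ± 0.12) and Rsad2 (1.10 ± 0.12) up and Stat2 (-0.33 ± 0.06) and Ifit2 (-0.50 ± 0.09) down. For NF-kappaB targets 17 of 23 tested members rose and 3 fell (18 and 3 list-adjusted), camera adjusted p = 9.9e-25. Examples were Cxcl1 (2.36 ± 0.10) and Nfkbiz (2.01 ± 0.08). In all 3876 genes differed, 2066 higher and 1810 lower (edgeR), with 1463 higher and 3634 lower under library size alone, which moved the median of all genes by -0.10. With replicate 3 alone in siprdx1+H2O2 the count was 2434.

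The fluvastatin effect on interferon-stimulated genes differed between the siRNA arms. In the interaction Rsad2 (1.62 ± 0.17), Ifit3 (1.36 ± 0.11), Ifit1 (1.09 ± 0.13) and Irf7 (0.50 ± 0.08) rose, and for the list 12 of 28 tested members rose (21 list-adjusted), camera adjusted p = 6.63e-40. Ifit3 went from 35.5 ± 1.13 to 16.3 ± 0.96 CPM with fluvastatin in siNC and from 41.8 ± 2.72 to 49.2 ± 2 CPM in siprdx1. For immediate early genes 11 of 24 tested members rose (15 list-adjusted), camera adjusted p = 9.23e-50. Among them were Fosb (1.57 ± 0.11), Fos (1.25 ± 0.09), Nr4a1 (1.07 ± 0.10) and Atf3 (1.03 ± 0.10). Outside this list Arc (1.87 ± 0.11) and Btg2 (1.06 ± 0.06) rose. For NF-kappaB targets 6 of 23 tested members rose (10 list-adjusted), camera adjusted p = 5.23e-17. These included Cxcl2 (1.41 ± 0.13), Cxcl1 (1.04 ± 0.15) and Ccl7 (0.79 ± 0.12). Fos ended at 204 ± 10.2 CPM in siNC and 221 ± 2.48 CPM in siprdx1. The falls included Ermp1 (-0.48 ± 0.09) and Slc38a2 (-0.52 ± 0.09). Macrophage markers moved up with the interferon list, as 0 of 17 tested members changed (10 higher list-adjusted, 11 at unadjusted p below 0.05, 8 by DESeq2, 1 by limma voom), camera adjusted p = 2.71e-07. In all 107 genes passed, 76 higher and 31 lower (edgeR). The count was 56 without siNC+H2O2 replicate 1, 69 without siNC+H2O2 replicate 3, 67 without siNC+H2O2+FV replicate 1, 59 without siNC+H2O2+FV replicate 2, 65 without siprdx1+H2O2 replicate 3, 53 without siprdx1+H2O2+FV replicate 1, 65 without siprdx1+H2O2+FV replicate 2 and 65 without siprdx1+H2O2+FV replicate 3, and 42 with replicate 3 alone in siprdx1+H2O2. Counts over single omissions were 0 to 3 for macrophage markers that rose.

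**Figure D3:**
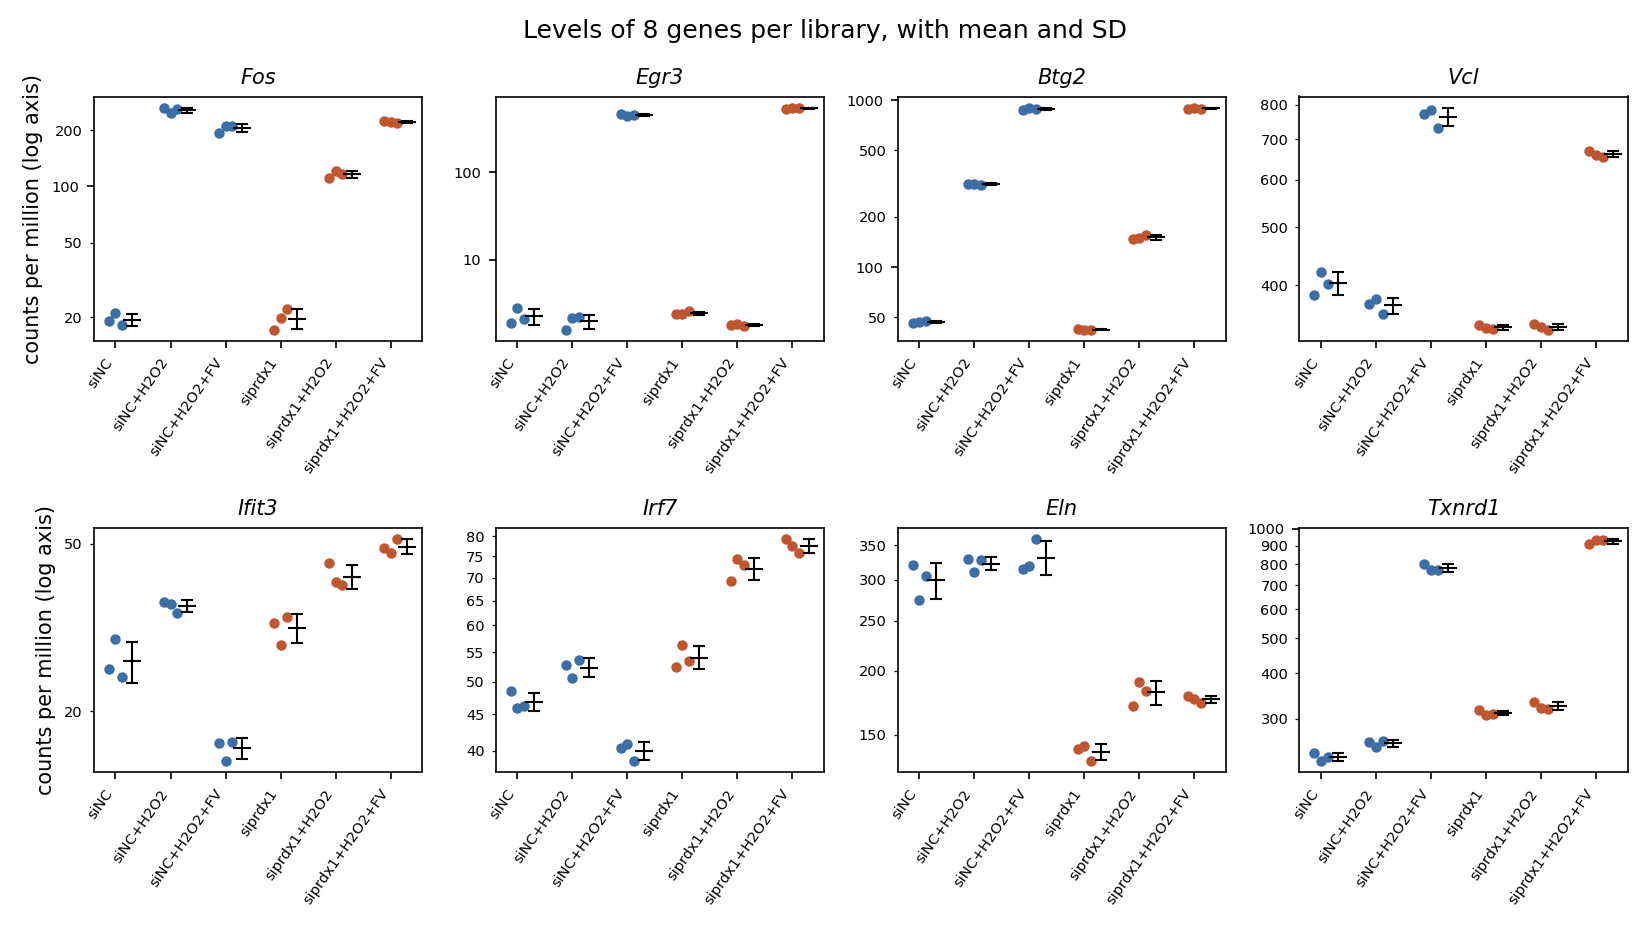
Levels of 8 genes by group in CPM on a log axis, with the 3 libraries of a group as points beside their mean and SD (siNC blue, siprdx1 orange). Fos after H2O2 averages 256 CPM in siNC and 116 CPM in siprdx1, and Ifit3 after fluvastatin 16.3 and 49.2 CPM.

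**Figure D4:**
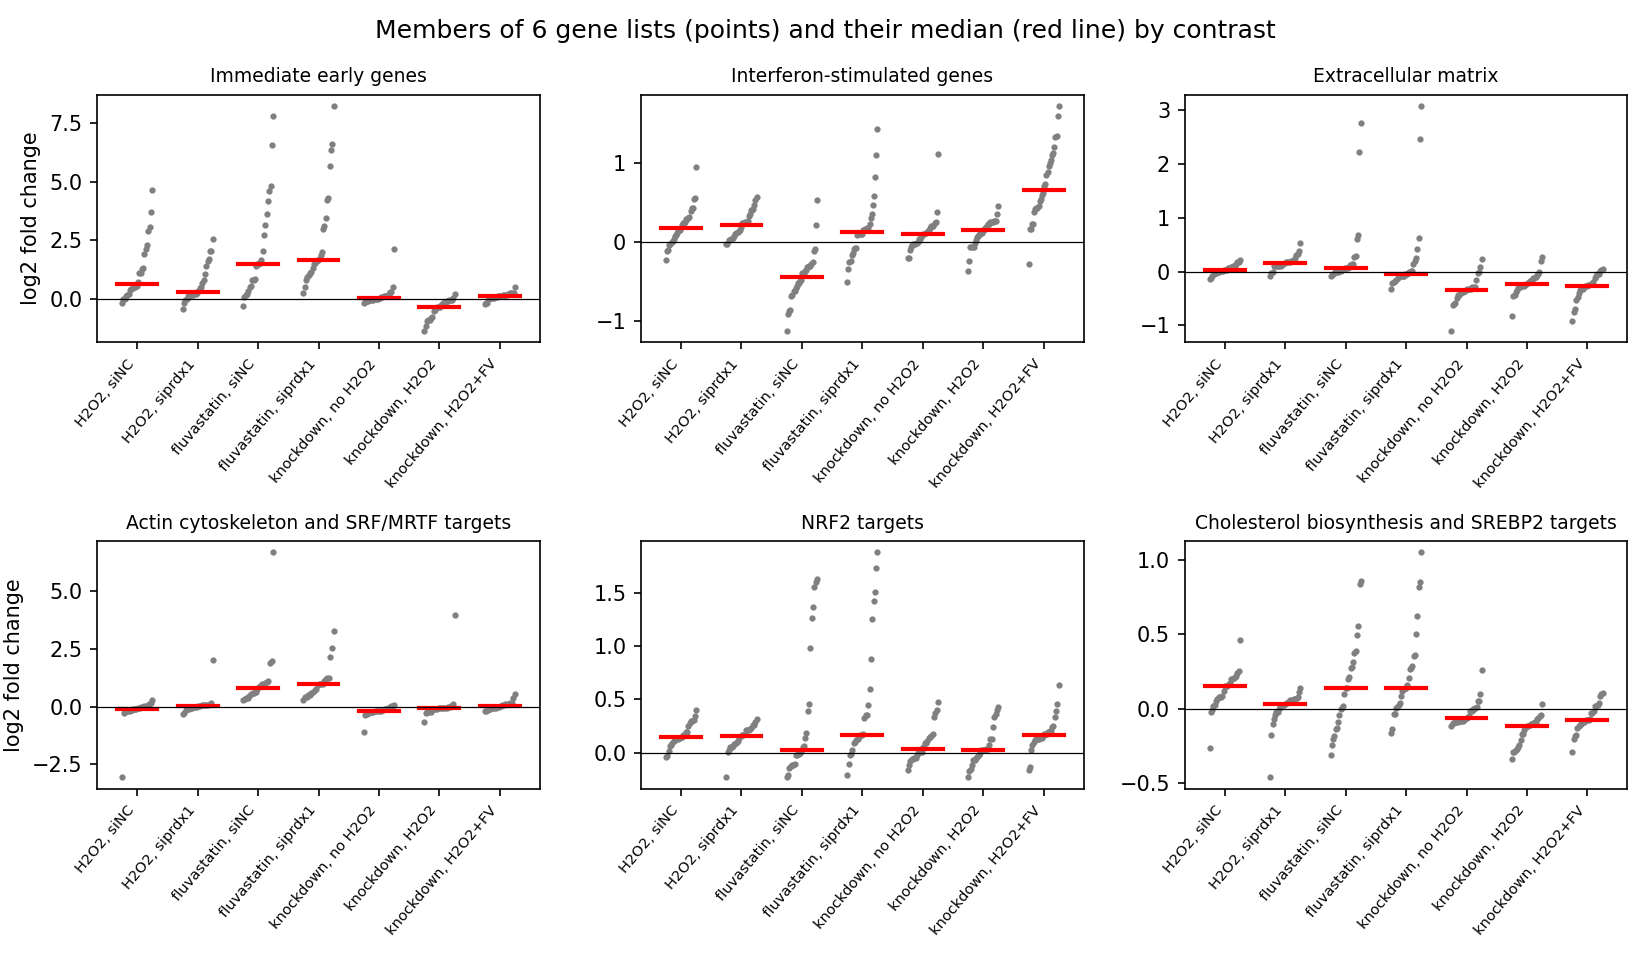
Log2 fold change of the tested members of 6 gene lists (grey points) and the list median (red line) in the 7 pairwise contrasts. Interferon-stimulated genes have a median of -0.43 for fluvastatin in siNC and 0.66 for knockdown after H2O2 and fluvastatin.

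Across the 16432 genes, which are not independent replicates, the fluvastatin effects in siNC and siprdx1 had Pearson r = 0.717 and Spearman rho = 0.57. With fluvastatin 1409 genes were higher in both arms against 279.9 for independent lists, and 1089 were lower in both against 205. The H2O2 effects in the arms had r = 0.524 and rho = 0.489, with 131 genes higher in both against 9.6 and 451 lower in both against 40.7. The H2O2 and fluvastatin effects in siNC share the siNC+H2O2 libraries with opposite sign. Their r was -0.288 and rho -0.353, beside r = -0.515 and rho = -0.458 in simulations of unchanged groups, and the covariance was -0.0515 beside -0.0294 simulated, a difference of -0.0221. Genes lower with H2O2 and higher with fluvastatin numbered 380 against 102 for independent lists, and genes higher with both 111 against 52.4. Part of the excess in opposite directions can come from the shared libraries, since 3 controls cannot be split.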

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

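The tests of a macrophage share, of siRNA sensing, and all fits with GC and length offsets were chosen after the data were seen, and the H2O2 and fluvastatin interactions themselves were planned. The genes and lists given here are those for which the interaction test found that an effect differed between the siNC and siprdx1 arms. The test (edgeR) gave 40 genes for H2O2 and 107 for fluvastatin.

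The log2 fold change with H2O2 was higher in siprdx1 than in siNC, by the differences given, for Scara5 (0.43), Sparcl1 (0.35), Thbs2 (0.39) and Abat (0.33). It was lower for Btg2 (-0.91), Fos (-1.15), Plk2 (-0.89), Ppp1r10 (-0.89), Nr4a1 (-1.0), Jun (-0.85), Fosb (-1.66), Dnajb1 (-0.72), Ccl7 (-0.67), Cxcl10 (-0.91) and Rhob (-0.51). Thbs2 did not pass without siNC+H2O2 replicate 3 (adjusted p = 0.0514). Abat did not pass without any 1 of siNC replicate 3, siNC+H2O2 replicates 1, 2 and 3, siprdx1 replicates 1, 2 and 3 and siprdx1+H2O2 replicate 3 (adjusted p 0.0583 to 0.0979). Ccl7 did not pass without any 1 of siNC replicate 3, siNC+H2O2 replicates 1 and 2 and siprdx1 replicates 1 and 3 (adjusted p 0.0655 to 0.106). Cxcl10 did not pass without any 1 of siNC replicates 1 and 3, siNC+H2O2 replicates 1, 2 and 3, siprdx1 replicates 1, 2 and 3 and siprdx1+H2O2 replicates 1, 2 and 3 (adjusted p 0.0515 to 0.172). Rhob did not pass without any 1 of siNC replicate 2, siNC+H2O2 replicates 1 and 3, siprdx1 replicates 2 and 3 and siprdx1+H2O2 replicate 3 (adjusted p 0.056 to 0.0868).

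The log2 fold change with fluvastatin was higher in siprdx1 for Btg2 (1.06), Arc (1.87), Fos (1.25), Fosb (1.57), Plk2 (1.13), Gdf15 (0.75), Nr4a1 (1.07), Atf3 (1.03), Dnajb1 (0.72), Hspb1 (0.44), Cxcl2 (1.41), Cxcl1 (1.04), Ccl7 (0.79), Nfkbiz (0.72), Ifit3 (1.36), Rsad2 (1.62), Ifit1 (1.09), Irf7 (0.50), Rhob (0.52), Rnd1 (0.77), Slc2a1 (0.51) and H1f2 (0.51), and lower for Fbn1 (-0.34), Pde3a (-0.64), Ermp1 (-0.48), Slc38a2 (-0.52), Ptpn14 (-0.46), Lox (-0.43), Thbs2 (-0.30) and Pdgfra (-0.27). Gdf15 did not pass without any 1 of siNC+H2O2 replicates 1, 2 and 3, siNC+H2O2+FV replicates 1 and 2, siprdx1+H2O2 replicates 1 and 3 and siprdx1+H2O2+FV replicates 1, 2 and 3 (adjusted p 0.055 to 0.138). Hspb1 did not pass without any 1 of the same libraries (adjusted p 0.0667 to 0.149). Ptpn14 did not pass without any 1 of siNC+H2O2 replicate 1, siNC+H2O2+FV replicate 2 and siprdx1+H2O2+FV replicates 1 and 3 (adjusted p 0.0594 to 0.0665). Rnd1 did not pass without any 1 of siNC+H2O2 replicates 1 and 2, siNC+H2O2+FV replicates 1 and 2, siprdx1+H2O2 replicates 1 and 3 and siprdx1+H2O2+FV replicates 1 and 2 (adjusted p 0.0573 to 0.0899). Lox did not pass without any 1 of siNC+H2O2 replicates 1 and 3, siNC+H2O2+FV replicates 1 and 2, siprdx1+H2O2 replicates 1 and 3 and siprdx1+H2O2+FV replicates 1, 2 and 3 (adjusted p 0.0503 to 0.0984). Thbs2 did not pass without any 1 of siNC+H2O2 replicates 1 and 3, siNC+H2O2+FV replicates 1, 2 and 3, siprdx1+H2O2 replicates 2 and 3 and siprdx1+H2O2+FV replicates 1, 2 and 3 (adjusted p 0.0728 to 0.157). Slc2a1 did not pass without any 1 of the libraries listed for Lox (adjusted p 0.0515 to 0.0961). Pdgfra did not pass without any 1 of the libraries listed for Gdf15 (adjusted p 0.0584 to 0.13). After H2O2, Btg2 was 309 to 317 CPM in siNC and 147 to 156 CPM in siprdx1. With fluvastatin it was 877 to 895 and 887 to 903 CPM, so its larger rise reflects a lower start. Both interactions share the H2O2 libraries.

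By camera, these lists moved as a set in the H2O2 interaction. Actin and SRF/MRTF targets moved up, and 0 of 20 tested members changed (0 list-adjusted, 2 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.0191, adjusted p = 0.396 with an estimated correlation. YAP/TEAD targets moved up, and 0 of 17 tested members changed (2 higher list-adjusted, 2 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), adjusted p = 0.000652. Extracellular matrix genes moved up, and 1 of 24 tested members rose (5 list-adjusted), adjusted p = 2.21e-08. Fibroblast and stromal markers moved up, and 0 of 11 tested members changed (1 higher list-adjusted, 3 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.000121. Cholesterol synthesis genes moved down, and 0 of 25 tested members changed (1 lower list-adjusted, 2 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), adjusted p = 4.74e-05. For p53 targets the test pointed down (adjusted p = 0.0248), with a median of 0.07 and a mean of -0.04. Here 2 of 24 tested members fell (2 list-adjusted), Btg2 and Plk2. Immediate early genes moved down, and 9 of 24 tested members fell (14 list-adjusted), adjusted p = 2.31e-49. Stress response genes moved down, and 0 of 23 tested members changed (1 lower list-adjusted, 5 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.0164. Heat shock genes moved down, and 1 of 18 tested members fell (1 list-adjusted), adjusted p = 0.00754. Steroid synthesis and Leydig identity genes moved down, and 1 of 21 tested members fell (1 list-adjusted), adjusted p = 0.0191, and the falling member is Nr4a1, which is also in the immediate early list. NF-kappaB targets moved down, and 1 of 23 tested members fell (6 list-adjusted), adjusted p = 6.08e-08. Cell cycle genes moved down, and 0 of 29 tested members changed (3 lower list-adjusted, 4 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.00396. Mitochondrially encoded transcripts moved down, and 0 of 13 tested members changed (0 list-adjusted, 2 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.00304, adjusted p = 0.254 with an estimated correlation. Glycolysis and hypoxia targets moved down, and 0 of 24 tested members changed (0 list-adjusted, 4 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.00903, adjusted p = 0.222 with an estimated correlation. Macrophage markers moved down, and 0 of 17 tested members changed (1 lower list-adjusted, 4 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), adjusted p = 8.28e-05. With 1 library left out the call ended for p53 targets without any 1 of siNC replicates 1 and 3, siprdx1 replicate 3 and siprdx1+H2O2 replicate 2 (adjusted p 0.0512 to 0.128), heat shock genes without siprdx1+H2O2 replicate 2 (adjusted p = 0.0653), steroid synthesis and Leydig identity genes without any 1 of siNC replicate 2, siNC+H2O2 replicate 3, siprdx1 replicate 2 and siprdx1+H2O2 replicate 1 (adjusted p 0.0573 to 0.0903), actin and SRF/MRTF targets without any 1 of siNC replicate 1, siprdx1 replicates 1 and 3 and siprdx1+H2O2 replicate 2 (adjusted p 0.0843 to 0.366), mitochondrially encoded transcripts without siprdx1+H2O2 replicate 2 (adjusted p = 0.0508) and glycolysis and hypoxia targets without any 1 of siNC replicate 2, siprdx1 replicate 2 and siprdx1+H2O2 replicate 1 (adjusted p 0.0529 to 0.131). Single omissions gave a count of 0 to 1 for YAP/TEAD targets that rose.

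By camera, these lists moved as a set in the fluvastatin interaction. Cholesterol synthesis genes moved up, and 0 of 25 tested members changed (0 list-adjusted, 5 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.00979. NRF2 targets moved up, and 0 of 24 tested members changed (0 list-adjusted, 7 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.00145, adjusted p = 0.0598 with an estimated correlation. Antioxidant enzymes moved up, and 0 of 27 tested members changed (1 higher list-adjusted, 7 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), adjusted p = 0.0201, adjusted p = 0.158 with an estimated correlation. The p53 targets moved up, and 3 of 24 tested members rose and 0 fell (4 and 1 list-adjusted), adjusted p = 0.00143. Immediate early genes moved up, and 11 of 24 tested members rose (15 list-adjusted), adjusted p = 9.23e-50. Stress response genes moved up, and 0 of 23 tested members changed (2 higher list-adjusted, 5 at unadjusted p below 0.05, 1 by DESeq2, 0 by limma voom), adjusted p = 0.0201. Heat shock genes moved up, and 2 of 18 tested members rose (4 list-adjusted), adjusted p = 0.000504. Steroid synthesis and Leydig identity genes moved up, and 1 of 21 tested members rose (1 list-adjusted), adjusted p = 0.0336, adjusted p = 0.065 with an estimated correlation, and the rising member is Nr4a1, which is also in the immediate early list. NF-kappaB targets moved up, and 6 of 23 tested members rose (10 list-adjusted), adjusted p = 5.23e-17. Interferon-stimulated genes moved up, and 12 of 28 tested members rose (21 list-adjusted), adjusted p = 6.63e-40. Cell cycle genes moved up, and 0 of 29 tested members changed (0 list-adjusted, 6 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.0047. Actin and SRF/MRTF targets moved up, and 0 of 20 tested members changed (0 list-adjusted, 3 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.0205, adjusted p = 0.395 with an estimated correlation, with a median of 0.11, a mean of -0.04 and the test pointing up. Oxidative phosphorylation genes moved up, and 0 of 31 tested members changed (0 list-adjusted, 3 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), adjusted p = 0.0047, adjusted p = 0.376 with an estimated correlation. Glycolysis and hypoxia targets moved up, and 1 of 24 tested members rose (2 list-adjusted), adjusted p = 7.96e-05, adjusted p = 0.065 with an estimated correlation. Histones moved up, and 1 of 9 tested members rose (2 list-adjusted), adjusted p = 7.06e-05. Macrophage markers moved up, and 0 of 17 tested members changed (10 higher list-adjusted, 11 at unadjusted p below 0.05, 8 by DESeq2, 1 by limma voom), adjusted p = 2.71e-07. Extracellular matrix genes moved down, and 3 of 24 tested members fell and 0 rose (4 and 2 list-adjusted), adjusted p = 0.00979, adjusted p = 0.301 with an estimated correlation. With 1 library left out the call ended for antioxidant enzymes without siNC+H2O2+FV replicate 2 (adjusted p = 0.0634), steroid synthesis and Leydig identity genes without any 1 of siNC+H2O2 replicate 3, siprdx1+H2O2 replicate 1 and siprdx1+H2O2+FV replicate 2 (adjusted p 0.0518 to 0.0739), actin and SRF/MRTF targets without any 1 of siNC+H2O2+FV replicate 1, siprdx1+H2O2 replicate 1 and siprdx1+H2O2+FV replicate 2 (adjusted p 0.0547 to 0.208) and extracellular matrix genes without any 1 of siprdx1+H2O2 replicate 2 and siprdx1+H2O2+FV replicate 3 (adjusted p 0.0714 to 0.119). These omissions also gave counts of 0 to 1 for matrix genes, cholesterol synthesis genes, stress response genes, antioxidant enzymes and glycolysis and hypoxia targets that rose, 1 to 2 for heat shock genes that rose and 1 to 3 for matrix genes that fell.

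The smaller rise of immediate early genes after H2O2 in knockdown cells had a list median of -0.32, with 9 of 24 genes past the threshold. A bias of GC content and transcript length as the whole cause is argued against, since with GC and length offsets the median was -0.32 and 9 of the 9 genes still passed. A lower share of macrophages in siprdx1+H2O2 stays open and cannot be told apart from it, because the macrophage markers had a median of -0.13, 0.187 above that of the list where 0.257 (2 SD of the markers) was needed. Chance as the source of the 40 genes of the interaction is left open, since the knockdown effect itself entered all 7 other splits that gave as many. A weaker early response to peroxide when Prdx1 is low may therefore be held only as a hypothesis.

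Under fluvastatin, interferon-stimulated genes were higher with knockdown by more than after H2O2 alone, with an interaction median of 0.48 and 12 of 28 past the threshold. With GC and length offsets the median was 0.41 and 11 of the 12 still passed, which argues against that bias as the whole cause. Sensing of the siRNA itself without regard to treatment would raise the list alike in all treatments, but the medians of the knockdown effect were 0.10, 0.16 and 0.66, and the last exceeded the first by a median of 0.52 ± 0.10 (SE from resampling genes, not libraries), for 26 of 28 genes. Sensing that differs between treatments was not tested. A higher macrophage share stays open and cannot be told apart, because macrophage markers had a median of 0.23, 0.243 below the list where 0.389 (2 SD) was needed. Chance as the source of the 107 genes is left open, since the knockdown effect entered 4 of the 5 other splits that gave as many, and an effect of Prdx1 on how fluvastatin lowers this program may be held only as a hypothesis.

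Other splits of the libraries were counted for each contrast. The 7 pairwise contrasts have 10 splits each, too few for a share under 0.05, since the real split alone makes 1 of 10. Their real counts were 1142, 4090, 383, 448, 652, 1293 and 3876, and the highest other split gave 0, or 1 for knockdown after H2O2 and fluvastatin. For the H2O2 effect in siNC, 4 splits part all 3 pairs of same-numbered libraries, and the highest other of these also gave 0. For the averaged knockdown effect 1 of 100 splits, the real one, gave 1542 or more and the highest other gave 606. This argues against chance, though the other splits mix the siRNA arms within a group. In the H2O2 interaction 8 of 100 splits gave 40 or more and the highest other gave 1002, and in the fluvastatin interaction 6 of 100 gave 107 or more and the highest other gave 372. All 7 other splits in the first, and 4 of 5 in the second, kept the siRNA labels of at least 2 more libraries in 1 treatment than in the other. The knockdown effect itself entered their contrast, so these shares do not test chance for an interaction. The split with 1002 genes kept 3 labels in 1 treatment and 0 in the other, so the structure it follows is the knockdown. Of the other splits that kept as many labels in both treatments, the highest of 40 in the first gave 0, and in the second 1 of 35 gave 372 and the next highest 0. These splits mix the siRNA arms within a group and were set apart only after the counts were seen, so chance is left open for both interaction counts. The split with 372 genes kept 2 labels in each treatment and points to a structure of the samples that was not tested.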

How the results depend on the processing

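Scaling by library size alone, GC and length offsets, and leaving out both siprdx1+H2O2 libraries at the GC extreme were chosen after the data were seen. With RLE size factors and limma voom every count of genes stayed within 1.5 times its value. The counts of genes moved further in these settings, for causes not tested except where fewer libraries or a size limit entered by construction. A minimum log2 fold change of 1 gave 163 for H2O2 in siNC, 585 for fluvastatin in siNC, 15 for knockdown without H2O2, 36 for knockdown after H2O2, 34 for knockdown after fluvastatin, 259 for H2O2 in siprdx1, 681 for fluvastatin in siprdx1, 7 for the H2O2 interaction, 20 for the fluvastatin interaction and 24 for the averaged knockdown. GC and length offsets gave 893 for knockdown without H2O2, 1252 for knockdown after H2O2, 1113 for knockdown after fluvastatin, 2319 for H2O2 in siprdx1, 198 for the H2O2 interaction, 315 for the fluvastatin interaction and 2704 for the averaged knockdown. The offsets with the replicate block gave 1857 for H2O2 in siNC, 1046 for knockdown without H2O2, 1483 for knockdown after H2O2, 1290 for knockdown after fluvastatin, 2551 for H2O2 in siprdx1, 256 for the H2O2 interaction, 443 for the fluvastatin interaction and 2955 for the averaged knockdown. Fits to only the groups compared gave 208 for knockdown without H2O2, 186 for knockdown after H2O2, 629 for H2O2 in siprdx1 and 24 for the H2O2 interaction. No low-count filter gave 97 for the H2O2 interaction and 281 for the fluvastatin interaction, and DESeq2 69 for the H2O2 interaction and 206 for the fluvastatin interaction. Leaving out both siprdx1+H2O2 libraries at the GC extreme, so that this group held 1 library assumed to vary like the others, gave 126 for knockdown after H2O2, 565 for H2O2 in siprdx1, 2434 for fluvastatin in siprdx1, 24 for the H2O2 interaction and 42 for the fluvastatin interaction. Leaving out 1 library at a time gave 653 to 1175 for H2O2 in siNC, 207 to 347 for knockdown without H2O2, 229 to 461 for knockdown after H2O2, 329 to 641 for knockdown after fluvastatin, 824 to 1261 for H2O2 in siprdx1, 26 to 54 for the H2O2 interaction and 53 to 136 for the fluvastatin interaction.

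With an estimated inter-gene correlation the lists past the threshold went from 15 to 8 for knockdown after H2O2, 10 to 6 after fluvastatin, 18 to 10 in the fluvastatin interaction and 14 to 8 for the average. Over all contrasts, for the lists reported here, 42 of 147 list calls ended with it, 13 with the offsets, 24 in at least 1 omission of a library and 0 with RLE size factors. With both GC-extreme libraries left out 13 of the 92 list calls in contrasts that use them ended. With only genes called in either arm, r between the arms was 0.85 for fluvastatin and 0.773 for H2O2, and leaving out 1 library gave 0.675 to 0.705 and 0.474 to 0.506. The cause was not tested.

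With the replicate block the counts were 1348 for H2O2 in siNC, 4267 for fluvastatin in siNC, 424 for knockdown without H2O2, 496 for knockdown after H2O2, 704 for knockdown after fluvastatin, 1400 for H2O2 in siprdx1, 3971 for fluvastatin in siprdx1, 41 for the H2O2 interaction, 129 for the fluvastatin interaction and 1659 for the averaged knockdown. It ended the call of 1 list, liver X receptor targets under the averaged knockdown (adjusted p = 0.0508), and moved no count over 1.5 times. Same-numbered libraries did not deviate together in every pair outside the H2O2 effect in siNC, where the lowest correlations were 0.058, -0.066, -0.059, -0.073, -0.006 and -0.012.

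Of 740 named results 712 passed, 179 of these failed in at least 1 setting that leaves out no single library, 180 in at least 1 omission of a library, and the sign of 8 turned in some setting. None of these had passed the test. Library size alone turned Cyp11a1 for fluvastatin in siNC to -0.04, Hmgcs1 for H2O2 in siprdx1 to -0.001, Prdx1 for fluvastatin in siprdx1 to -0.052 and Hmox1 in the H2O2 interaction to -0.011. The omission of both GC-extreme libraries turned Hmgcs1 in the fluvastatin interaction to 0.005, and the latter was 0.07 with GC and length offsets and 0.071 with these and the replicate block. Leaving out 1 library gave -0.029 to 0.051 for Star (H2O2 in siNC), -0.062 to 0.12 for Hmgcs1 (H2O2 in siprdx1) and -0.004 to 0.123 for Prdx1 (fluvastatin in siprdx1). It gave -0.18 to 0.003 for Hmgcs1 and -0.031 to 0.057 for Hmox1 in the H2O2 interaction, and -0.096 to 0.087 for Hmgcs1 and -0.056 to 0.032 for Hmox1 in the fluvastatin interaction. The cause was not tested. With DESeq2, 4 named results had no adjusted p..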

Other observations

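In this part the within-group axis and the fit with GC and length offsets were chosen after the data were seen. Further lists were tested for fluvastatin in siNC. Among ferroptosis regulators, 7 of 19 tested members rose and 0 fell (7 and 2 list-adjusted), camera adjusted p = 4.51e-07. These included Hmox1 (1.26 ± 0.05) and Sat1 (0.96 ± 0.05). Of p53 targets 10 of 24 tested members rose and 4 fell (11 and 4 list-adjusted), camera adjusted p = 0.000219. Examples were Pmaip1 (1.76 ± 0.16) and Mdm2 (0.76 ± 0.06). Among glycolysis and hypoxia targets, 5 of 24 tested members rose and 4 fell (6 and 5 list-adjusted), camera adjusted p = 0.0363, adjusted p = 0.29 with an estimated correlation, with a median of -0.07, a mean of 0.11 and the test pointing up, and library size alone gave 5 higher and 10 lower. These included Hk2 (1.92 ± 0.05), Slc2a1 (1.31 ± 0.08) and Vegfa (1.05 ± 0.07). For apoptosis genes 4 of 23 tested members rose and 8 fell (4 and 8 list-adjusted), camera adjusted p = 0.506, with a median of -0.14, a mean of 0.02 and the test pointing down. Among them were Bcl2l11 (1.01 ± 0.09) and Bmf (-1.36 ± 0.09) in opposite directions. Among liver X receptor targets, 1 of 13 tested members rose and 3 fell (1 and 4 list-adjusted), camera adjusted p = 0.339. Among autophagy and lysosome genes, 3 of 23 tested members rose and 2 fell (3 and 2 list-adjusted), camera adjusted p = 0.514. Among Sertoli cell markers, 1 of 12 tested members rose and 2 fell (1 and 2 list-adjusted), camera adjusted p = 0.44. An example was Sox9 (1.30 ± 0.08). Among endothelial markers, 0 of 7 tested members changed (0 list-adjusted, 0 at unadjusted p below 0.05, 0 by DESeq2, 0 by limma voom), camera adjusted p = 0.764. Among fibroblast markers, 2 of 11 tested members fell (2 list-adjusted), camera adjusted p = 0.0801. An example was Tcf21 (-1.01 ± 0.07).

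The glycolysis call ended when siNC+H2O2 replicate 2 or siNC+H2O2+FV replicate 3 was left out (adjusted p 0.0542 to 0.0773). Among these lists the p53 count that fell became 2 without siNC+H2O2 replicate 1 or siNC+H2O2+FV replicate 2, the apoptosis count that fell became 5 without siNC+H2O2+FV replicate 1 and the glycolysis count that fell became 1 without siNC+H2O2 replicate 1 or siNC+H2O2+FV replicate 2 and 2 without siNC+H2O2 replicate 3. Small counts over single omissions were 0 to 1 for ferroptosis regulators that fell, 0 to 1 for liver X receptor targets that rose, 1 to 2 for autophagy and lysosome genes and Sertoli cell markers that fell and 1 to 2 for Sertoli cell markers that rose.

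The knockdown effects without H2O2 and after fluvastatin shared 157 lower genes against 6.5 for independent lists, with no library in common. Across genes the H2O2 and fluvastatin interactions had r = -0.565 beside -0.496 in simulations of unchanged groups that share the same H2O2 libraries, and 25 genes fell in the first and rose in the second against 0.2 for independent lists. Part of this can come from the shared libraries. The share of long noncoding RNAs in siprdx1 was 0.951% ± 0.015 without H2O2, 0.683% ± 0.012 after H2O2 and 0.779% ± 0.019 with fluvastatin (SD, n = 3). An axis of variation within groups held 17.4% of the within-group variance, and its loadings had a Spearman rho of -0.646 with transcript GC content and 0.198 with transcript length across genes.

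After H2O2 in siNC, 164 of 1598 noncoding genes were lower and 21 higher, with a median log2 fold change of -0.21 beside 0.01 for coding genes. With GC and length offsets and the replicate block 98.8% of the lower genes (162 of 164) still passed, against that bias as the whole cause. Genomic DNA in the untreated libraries would make the counts of silent coding genes fall alike, but the share of counts on 8314 coding genes under the filter was 0.983 of its level in siNC (0.96 to 1.003 over pairs of libraries), while sense-intronic transcripts and those awaiting experimental support stood at 0.742 (0.663 to 0.831). A loss of short-lived or nuclear noncoding RNA after peroxide may be a hypothesis to follow, and unspliced RNA was not tested.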
